A study of Homo sapiens with 6 samples.

How the data were processed

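Gene expression was measured on 6 Affymetrix Human Genome U133 Plus 2.0 arrays, 1 per sample, from CL1-0, an established human lung adenocarcinoma cell line. Per the labels, 3 samples came from cells carrying an empty vector and 3 from cells overexpressing YWHAZ, which encodes the 14-3-3 zeta protein, all kept in 1000 µg/ml of the selection drug G418 and 10% serum. Groups and replicate numbers were taken from the sample titles. The titles call the replicates biological but do not say whether they came from separate transfections or cultures, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, RNA was extracted with Trizol, amplified by PCR and transcription into biotin-labelled cRNA, and hybridised to the arrays.

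The deposited table holds 1 value for each of 54675 probe sets in each of the 6 samples, and these values are linear ratios. In all 54675 probe sets the geometric mean of the middle pair of the 6 values was 1 within 1e-05, so each value is the probe set's ratio to its own median over the 6 arrays, taken on a log scale. The ratios range from 0.0833 to 11.2. GCRMA, a background correction and normalization for Affymetrix arrays, was used per the submitters' processing notes; its version and the step that produced the ratios are not given in the sources used here. Because each probe set was divided by its own median, the level of a transcript is not in the table. Distance from background could not be judged, no probe set could be called detected, and levels of different genes could not be set against each other. How far background noise narrows the change of a weakly expressed gene is therefore unknown, and so is the true size of such a fold. The number of arrays, 3 per group, limits the precision.

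The tests differ from the plan written before the data were examined in 3 ways, because the plan expected expression levels and the table holds ratios. First, log2 of the ratio was tested directly, and the planned pseudocounts of 1 and 16 became alternatives. Second, the planned filter on low values, above the median of the table in at least 3 samples, keeps 54607 of 54613 probe sets and removes almost nothing. The filter used in its place kept probe sets whose highest ratio over the 6 arrays was at least 1.1-fold their lowest; it ignores the groups and was chosen after seeing the data. It kept 25126 probe sets (46.0%) and left out 29487. Last, the planned choice of the probe set with the highest mean to stand for a gene has no meaning for ratios. A gene's value was instead the mean log2 ratio of its kept probe sets, which the plan listed as an alternative. Flat probe sets left out by the range filter do not enter this mean, so a gene's change can be larger than over all its probe sets. For tested genes, the probe sets counted below are the kept ones.

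The 62 control probe sets of the array were left out of the tests and used to describe the arrays. Probe sets were named from the platform's annotation: 41091 had 1 gene symbol, 1801 had several and 11721 had none listed. Of those with 1 symbol, 41037 were matched through their Entrez identifier to current RefSeq symbols of the assembly GRCh38.p14, and the rest kept the platform's symbol. Probe sets with several symbols or none were tested but not named. The kept probe sets stood for 11767 genes, 5326 of them with more than 1 probe set. GRCh38.p14 was used only for names and for which genes neighbour each other; probe positions within transcripts were not used here.

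YWHAZ-overexpressing samples were compared with vector controls by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), once over probe sets and once over genes. P-values were adjusted by the Benjamini-Hochberg method over the probe sets or genes tested, with a threshold of 0.05. Standard errors are the moderated ones from limma. In advance, 28 gene lists were fixed for the study's subject and the cells, and 26 of them had at least 5 kept genes and were tested with limma's camera, with a preset correlation of 0.01 between genes and adjustment over the 26 lists. Beside it, camera with an estimated correlation and fry were run, and members were also counted with adjustment over each list alone. Of these lists, 4 hold markers of other cell types (fibroblasts, endothelium, leukocytes, neuroendocrine cells). The result of 1 tested list is not reported here. Older symbols in the lists were updated, WISP1 to CCN4, WISP2 to CCN5, DDX58 to RIGI, CTGF to CCN2 and CYR61 to CCN1.

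The rule for named genes, also fixed in advance, takes YWHAZ with all its probe sets; the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups do not overlap; from each list up to 4 members past the threshold with the largest change; every kept member of the 14-3-3 family; and CDH1, VIM, CTNNB1, CDH2 and SNAI2. The pipeline was tested on simulated data with the 25126 probe sets and the spread of this comparison. It recovered 4 of 50 probe sets changed 1.2-fold, 31 of 50 changed 1.5-fold, 46 of 50 changed 2-fold and 50 of 50 changed 4-fold, with 6 false calls. Only 50 probe sets were changed at each size, whereas 9983 passed in the data. The adjusted threshold depends on how many probe sets change, so these recovery rates do not carry over to the data. Of 26 simulated gene lists, the 1 that had been shifted was called and none of the others. The simulated genes were drawn independently, so this does not check the list test where genes are correlated.

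Alternative settings fixed in advance were no filter, the planned filters as written, quantile normalization, centring each array on its median, trended and robust variance, the replicate number as a block, each sample left out in turn, the pseudocounts of 1 and 16, the planned single probe set per gene, camera with an estimated correlation and fry. A range filter of 1.2-fold, the probe set with the largest range for each gene, and camera on ranks were added after seeing the data. A single value per array, such as the mean of the spike-in controls, was compared between the groups by a 2-sided exact permutation test, which cannot go below 0.1 with 3 samples against 3.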

Results

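The data comprise 6 expression arrays of CL1-0 cells, a lung adenocarcinoma line described by the submitters as weakly invasive: 3 vector controls and 3 samples overexpressing YWHAZ. The series asks what raised 14-3-3 zeta, an adaptor that binds phosphorylated proteins, changes in such cells with regard to invasion and metastasis. Values are ratios to each probe set's median over the 6 arrays, so they give differences between samples and no expression levels. Differences are given as log2 of YWHAZ-overexpressing over vector control with the standard error (SE) from limma, n = 3 per group, and adjusted p-values are those of limma with Benjamini-Hochberg adjustment over all genes unless camera is named. The number of arrays limits the precision, and p-values measure only the spread between these samples.

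YWHAZ was higher in the cells labelled as overexpressing it, by 1.33-fold on the mean of its probe sets and up to 1.73-fold on a single one. Its probe set 200641_s_at had a ratio of 0.743 ± 0.0529 (SD, n = 3) in vector controls and 1.28 ± 0.0403 in YWHAZ samples, a log2 difference of 0.79 ± 0.066 (SE, adjusted p = 0.000254 over probe sets). Probe set 200638_s_at rose from 0.842 ± 0.0237 to 1.22 ± 0.0565, which is 1.45-fold (adjusted p = 0.000573). Probe set 200640_at rose from 0.855 ± 0.00383 to 1.18 ± 0.0155, or 1.38-fold (adjusted p = 0.000451). The remaining YWHAZ probe sets did not pass: 200639_s_at was 1.06-fold higher (adjusted p = 0.268) and 214848_at 1.16-fold higher (adjusted p = 0.152). The mean over all 5 probe sets was 0.41 ± 0.044 (adjusted p = 0.000383), and this gene-level call is lost if 214848_at, the probe set with the highest mean ratio, alone stands for YWHAZ (0.21, adjusted p = 0.159). The gene-level rise of 1.33-fold was close to the median of 1.27-fold among all genes called. Which of the YWHAZ probe sets lie in the transfected sequence was not determined, and a probe set outside it does not check the labels.

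**Figure D1:**
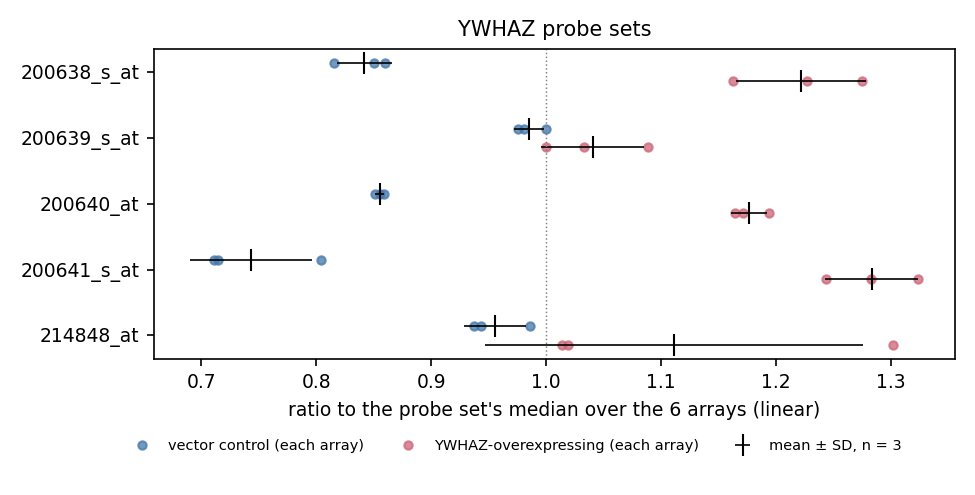
Ratio of each YWHAZ probe set to its median over the 6 arrays (linear axis), with 1 point per array and the mean ± SD of 3 arrays per group. For 200638_s_at, 200640_at and 200641_s_at the 3 YWHAZ-overexpressing arrays lie well above the 3 vector controls, with a fold of 1.45, 1.38 and 1.73; the other probe sets differ by 1.06-fold and 1.16-fold and did not pass the test.

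Within the 14-3-3 family, YWHAE and YWHAH rose beside YWHAZ and SFN fell. Of 6 kept family genes, YWHAZ included, 4 rose, 1 fell and 1 did not pass (5 rose and 1 fell adjusted over the list alone). YWHAE rose by 0.43 ± 0.047 (adjusted p = 0.000463), through 210317_s_at (1.67-fold) more than 210996_s_at (1.08-fold, adjusted p = 0.116). YWHAH rose by 0.33 ± 0.045 (adjusted p = 0.00111) on its only kept probe set. The range filter left out its probe sets 236559_at (-0.028) and 242325_at (-0.015). For YWHAQ it left out 212426_s_at (0.026) and 213699_s_at (-0.0069). YWHAQ rose by 0.12 ± 0.041 (adjusted p = 0.0455), a call lost in 10 alternative settings, and YWHAB stood at 0.11 ± 0.041 (adjusted p = 0.0659). SFN, the epithelial family member 14-3-3 sigma, fell by 0.26 ± 0.057 (adjusted p = 0.00905), although none of its 3 probe sets passed by itself and the call was lost in 3 alternative settings. The YWHAG probe set varied by less than 1.1-fold and was not tested. As a group the family had a median of 0.23 and did not pass camera (adjusted p = 0.226), though it did without the range filter (adjusted p = 0.0230). With the filter and an estimated correlation the adjusted p = 0.468.

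The array's own controls differed between the groups. The bacterial transcripts added at hybridisation had a mean log2 ratio of 0.43 ± 0.0419 (SD, n = 3) in vector controls and -0.41 ± 0.0303 in YWHAZ samples, a difference of -0.84, and all 18 probe sets for them were lower in YWHAZ samples, by 1.32-fold to 2.11-fold. Probe sets for the poly-A spike-ins, transcripts that can be added before labelling, differed by -0.027. Without levels it is unknown whether these transcripts were added, so this small difference does not show that labelling was equal. Ribosomal RNA probe sets, which detect carried-over ribosomal RNA, were lower in YWHAZ samples by 1.80-fold. The 5′ minus 3′ difference of the ACTB control probe sets, a measure of transcript integrity and of the length of the labelled product, rose from -0.24 ± 0.025 to 0.24 ± 0.023, and that of GAPDH from -0.11 ± 0.031 to 0.14 ± 0.020. Each of these 5 measures separated the groups completely, with an exact permutation p = 0.1, the smallest that 3 against 3 can give. They move with the groups, and so with every gene group described here.

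**Figure D2:**
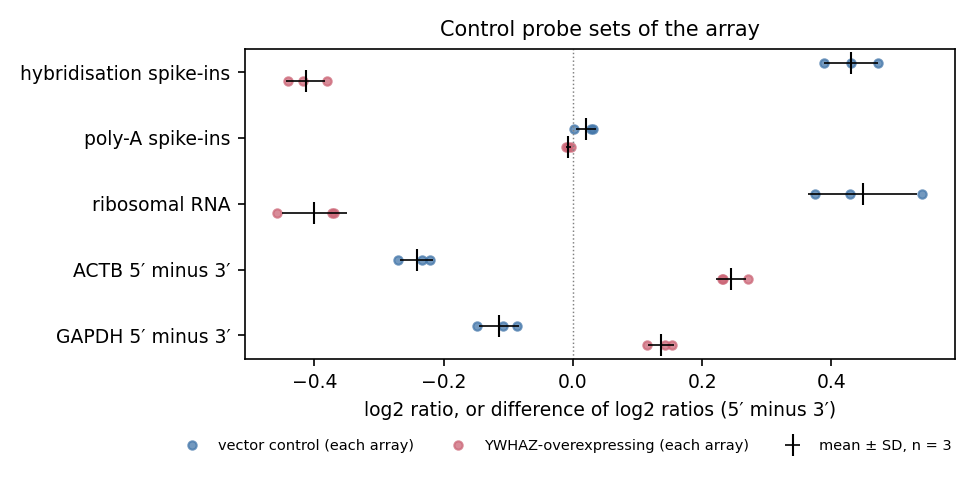
Mean log2 ratio of the spike-in and ribosomal RNA control probe sets, and the 5′ minus 3′ difference of log2 ratios for ACTB and GAPDH, with 1 point per array and the mean ± SD of 3 arrays per group. Hybridisation spike-ins lie near 0.43 in vector controls and near -0.41 in YWHAZ-overexpressing samples. Poly-A spike-ins differ by -0.027, and whether they were added is unknown.

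Expression differed widely between the 2 kinds of cell, mostly by small amounts. Of 11767 genes tested, all kept by the range filter, 5417 (46.0%) passed the threshold, 3426 of them higher and 1991 lower in YWHAZ-overexpressing cells. Without the range filter 4965 genes passed out of a larger number tested, so the share depends on the filter. The median size among the 5417 genes was 1.27-fold, and 4531 (83.6%) changed by less than 1.5-fold. At least 2-fold changes were seen for 124 genes that rose and 128 that fell, a total of 252. That total is 159 without the range filter, 458 if the probe set with the largest range stands for each gene, 66 on log2 of the ratio plus 1 and 0 on log2 of the ratio plus 16, where the added constant shrinks every difference and limma still called 5305 genes. At 8-fold and more, 4 genes were higher and 15 lower. The groups did not overlap for 64.4% of the genes tested, against the 10% that chance gives for 3 against 3. Probe sets of a gene could disagree: among 1771 genes with more than 1 probe set past the threshold, 313 had them in both directions.

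The gene with the largest fall was TIMP1, a secreted inhibitor of matrix metalloproteinases, at -6.70 ± 0.056 (adjusted p = 3.60e-09), 104-fold lower on its only kept probe set. Next came NEFL and NEFM, neighbouring genes for the light and medium neurofilament subunits of neurons. NEFL fell 86.1-fold (-6.43 ± 0.054), with its 3 probe sets between -6.20 and -6.77, and NEFM 62.9-fold (-5.98 ± 0.068). SPARCL1, a secreted matrix-associated protein, fell 27.0-fold (-4.75 ± 0.10), the presynaptic scaffold gene ERC2 16.3-fold (-4.03 ± 0.12) and the ubiquitin ligase gene TRIM6 14.1-fold (-3.82 ± 0.099). FOXA1, a pioneer transcription factor of endodermal epithelia, fell 13.7-fold (-3.78 ± 0.079), both probe sets being lower. Falls were also measured for F2RL2, a protease-activated receptor (-3.70 ± 0.090), KCNJ2, an inward-rectifier potassium channel (-3.61 ± 0.17), and TMSB4X, which encodes the actin-sequestering thymosin beta-4 (-3.61 ± 0.054). TMSB4X rests on 1 probe set that near-identical gene copies could share, so its identity is uncertain. FLRT2, a membrane protein of cell adhesion, fell by 3.45 on the log2 scale, with its probe sets at -5.13, -4.60 and -0.63. The last passed over probe sets (adjusted p = 0.0486), and the gene's call is lost if it alone stands for FLRT2 among genes so represented (adjusted p = 0.0523). CAV1, the main coat protein of caveolae, fell 9.86-fold (-3.30 ± 0.051, adjusted p = 1.00e-07), at -3.30 on each of its 2 probe sets.

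PLAC8, a small cysteine-rich protein first described in placenta, had the largest rise, at 5.72 ± 0.10 (adjusted p = 2.10e-07), 52.7-fold on its only kept probe set. AGTR1, the type 1 angiotensin II receptor, rose 15.4-fold (3.95 ± 0.081), its probe sets lying at 3.67 and 4.22. The phosphoinositide-binding adaptor gene PLEKHA2 rose 10.7-fold (3.43 ± 0.11), and DACH1, a transcriptional co-regulator, 9.32-fold (3.22 ± 0.062) with both probe sets above 3. Further rises were those of SLC25A21, a mitochondrial carrier (2.91 ± 0.28), NIPA1, a magnesium transporter (2.83 ± 0.099), FAT4, a large atypical cadherin (2.70 ± 0.10), RASSF9 (2.60 ± 0.15), CNKSR2, a scaffold of Ras signalling (2.58 ± 0.10), the ETS transcription factor ERG (2.56 ± 0.21) and PRICKLE1, a planar cell polarity gene (2.54 ± 0.11). PDCD6IPP2, a pseudogene, stood at 2.90 ± 0.087 on a probe set that may also bind its near-identical relatives, so which copy rose is uncertain. The rule that named these 24 genes required groups that do not overlap. The highest adjusted p among them was 0.000272 (limma), for SLC25A21.

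**Figure D3:**
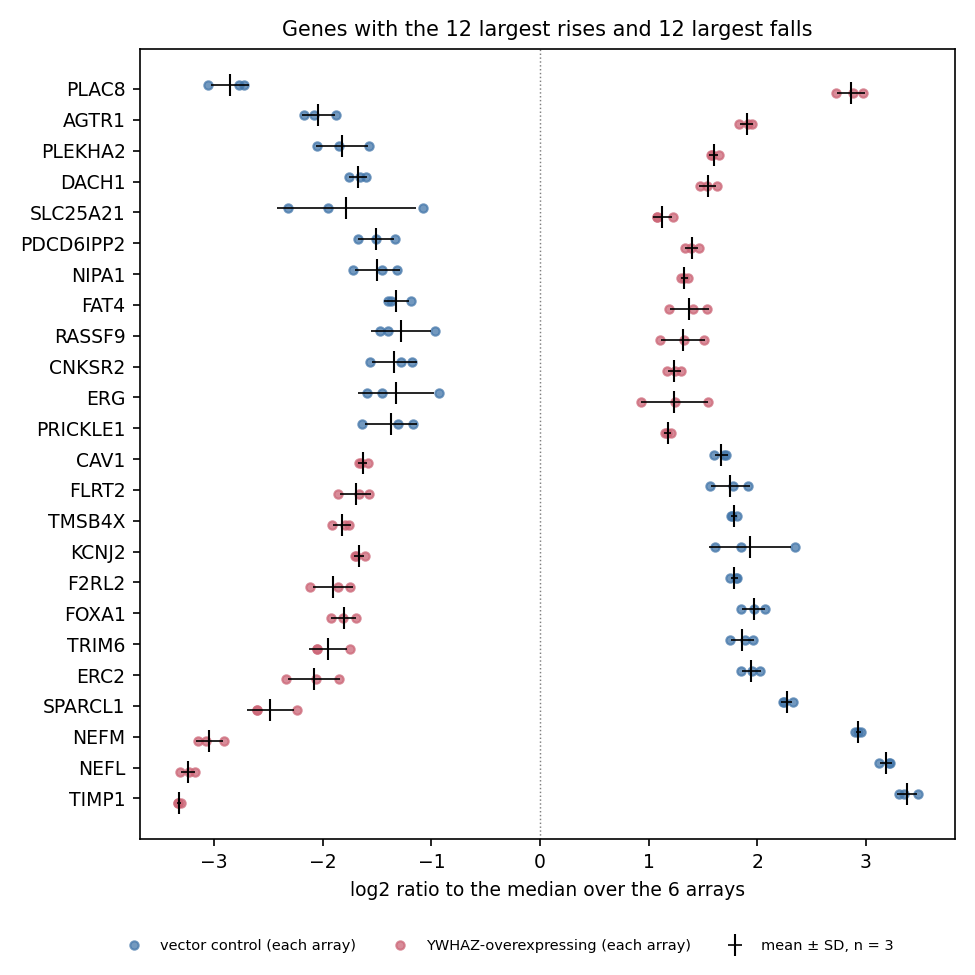
Log2 ratio to the median over the 6 arrays for the genes with the 12 largest rises and the 12 largest falls, with 1 point per array and the mean ± SD of 3 arrays per group. Genes were chosen among those whose groups do not overlap; PLAC8 is highest with a difference of 5.72 and TIMP1 lowest with -6.70.

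Markers of epithelial and mesenchymal state changed in single genes, and neither list passed as a group. Of all genes tested 46.0% passed the threshold, a share to set beside the member counts of each list. Among 17 kept genes for epithelial junctions and keratins, 4 rose, 1 fell and 12 did not pass, with the same counts adjusted over the list alone. The desmosomal genes DSP and JUP rose most, DSP by 1.77 ± 0.094 (3.42-fold, adjusted p = 2.59e-05) and JUP by 1.01 ± 0.11 (2.02-fold, adjusted p = 0.000358). The mucin gene MUC1 fell by 0.39 (adjusted p = 0.0136), with its probe sets at -0.63 and -0.14, of which the latter did not pass. E-cadherin, CDH1, stood at 0.071 ± 0.070 (adjusted p = 0.415) on 1 kept probe set. Of 19 mesenchymal markers and EMT (epithelial to mesenchymal transition) factors, 6 rose, 2 fell and 11 did not pass, again the same adjusted over the list alone. COL3A1, a fibrillar collagen, rose by 1.89 ± 0.092 (3.70-fold, adjusted p = 1.69e-05) on 3 probe sets, and COL5A2 by 0.68 ± 0.049 (1.60-fold, adjusted p = 8.32e-05). POSTN, a matrix protein, rose by 0.89 ± 0.062 with its probe sets at 1.58 and 0.20, of which the lower did not pass. LOX, which crosslinks collagen, fell by 0.58 (adjusted p = 0.00140), with its probe sets at -0.84 and -0.31, of which the latter did not pass. Vimentin, VIM, stood at 0.058 ± 0.055 (adjusted p = 0.392): 201426_s_at stood at 0.27 (adjusted p = 0.00501) and 1555938_x_at at -0.15 (adjusted p = 0.254). N-cadherin (CDH2) and SNAI2 varied by less than 1.1-fold on every probe set and were not tested, which at unknown level says nothing of their expression. Camera's adjusted p was 0.912 for the epithelial and 0.350 for the mesenchymal genes.

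Beta-catenin itself and several Wnt genes changed, and neither Wnt list passed as a group. CTNNB1, which encodes beta-catenin, fell by 0.27 ± 0.057 (1.21-fold, adjusted p = 0.00733). Its probe set 201533_at passed by itself (adjusted p = 0.00221) and 223679_at did not (0.0912). The call is lost if 223679_at alone stands for the gene. A further probe set, 1554411_at, stood at -0.0098, varied by less than 1.1-fold and was not tested. Among 14 beta-catenin/TCF target genes, 4 rose, 2 fell and 8 did not pass, with the same counts adjusted over the list alone. CCND1, which encodes cyclin D1, rose by 1.23 ± 0.086, but its probe sets stood at 2.27 and 0.18 and the lower did not pass. The secreted Wnt inhibitor DKK1 fell by 0.56 ± 0.080 (adjusted p = 0.00133), MYC rose by 0.35 ± 0.046 (adjusted p = 0.000854) and BIRC5, which encodes survivin, by 0.35 ± 0.053 (adjusted p = 0.00180). Of 30 Wnt pathway components, 10 rose, 7 fell and 13 did not pass (11 and 7 adjusted over the list alone). WNT5A, a ligand of the beta-catenin-independent branch, fell 3.14-fold (-1.65 ± 0.053, adjusted p = 2.73e-06) on both probe sets, and DKK3 rose 2.46-fold (1.30 ± 0.096, adjusted p = 9.54e-05). Camera's adjusted p was 0.963 for the targets and 0.845 for the components.

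Genes for matrix breakdown and adhesion changed in both directions. Among 20 kept extracellular proteases and inhibitors, 4 rose, 7 fell and 9 did not pass (5 and 7 adjusted over the list alone). Besides TIMP1, the stromelysin gene MMP10 fell 3.20-fold (-1.68 ± 0.18, adjusted p = 0.000400), while TIMP2, another metalloproteinase inhibitor, rose 1.75-fold (0.81 ± 0.050, adjusted p = 4.82e-05). In the list of integrins and focal adhesion, 3 of 23 genes rose, 5 fell and 15 did not pass, whether adjusted over all genes or over the list alone. Next to CAV1, the integrin subunit gene ITGAV rose 2.62-fold (1.39 ± 0.045, adjusted p = 2.87e-06), the laminin gene LAMB1 fell 2.34-fold (-1.23 ± 0.063, adjusted p = 2.35e-05) and ITGA5, the fibronectin receptor subunit, fell 1.79-fold (-0.84 ± 0.11, adjusted p = 0.000866). Camera passed neither list (adjusted p = 0.217 and 0.350).

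Genes tied to invasion and metastasis of lung cancer changed both ways. Of 19 kept, 4 rose, 7 fell and 8 did not pass, the same adjusted over the list alone. TFPI2, a secreted serine protease inhibitor, fell 5.33-fold (-2.41 ± 0.091, adjusted p = 6.05e-06) and MET, the receptor of hepatocyte growth factor, 4.89-fold (-2.29 ± 0.12, adjusted p = 2.51e-05). VEGFC, a lymphangiogenic growth factor, rose 4.59-fold (2.20 ± 0.071, adjusted p = 2.87e-06). The list did not pass camera (adjusted p = 0.217). CAV1 and MET belong to a run of 4 consecutive kept genes on chromosome 7 that all fell, with TES at -3.17 and CAV2 at -3.08. TES and CAV2 were singled out after their values were seen. On chromosome 7 as a whole 35.3% of the genes were higher, against 54.6% of all placed genes. It held 18 genes at least 2-fold lower and 4 at least 2-fold higher. Whether falls of single genes on this chromosome are separate effects was not tested.

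Many proliferation genes rose in YWHAZ-overexpressing cells by small amounts. Of 39 kept cell cycle genes, 24 rose, 7 fell and 8 did not pass, with the same counts adjusted over the list alone, and the median was 0.26. The mitotic kinesin gene KIF20A rose by 0.87 ± 0.050 (1.83-fold, adjusted p = 3.66e-05) and the mitotic kinase gene PLK1 by 0.61 ± 0.052 (1.52-fold, adjusted p = 0.000165). CDK6, a cyclin D-dependent kinase of G1, fell 4.09-fold (-2.03 ± 0.065, adjusted p = 2.73e-06), on all 4 kept probe sets. The list passed camera as higher (adjusted p = 0.0440), and the call is lost with an estimated correlation (adjusted p = 0.421). It is also lost without vector control replicate 1 (adjusted p = 0.0750), without YWHAZ replicate 2 (adjusted p = 0.0571), after quantile normalization (adjusted p = 0.0611) and in 4 further settings. The hybridisation controls differed by -0.84 and the ACTB 5′ minus 3′ measure by 0.49 between the same groups.

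The unfolded protein and ATF4 response had the smallest camera p of the 26 lists, and most of its genes fell. Of 34 kept genes, 24 fell, 4 rose and 6 did not pass (25 and 5 adjusted over the list alone), with a median of -0.38. STC2, a secreted glycoprotein hormone, fell 6.87-fold (-2.78 ± 0.076, adjusted p = 1.28e-06) and SESN2, an inhibitor of mTORC1 signalling, 5.02-fold (-2.33 ± 0.082, adjusted p = 3.96e-06). DDIT3, which encodes the stress transcription factor CHOP, fell 3.49-fold (-1.80 ± 0.082, adjusted p = 1.30e-05), and CHAC1, a glutathione-degrading enzyme induced by ATF4, 3.17-fold (-1.66 ± 0.066, adjusted p = 6.62e-06). As background, these 4 genes are known targets of the ATF4 branch. Camera gave an adjusted p = 1.93e-09 and, with an estimated correlation, an adjusted p = 0.0907, which does not pass. The hybridisation controls were also lower in these samples, by -0.84, and the ACTB 5′ minus 3′ measure was higher by 0.49.

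**Figure D4:**
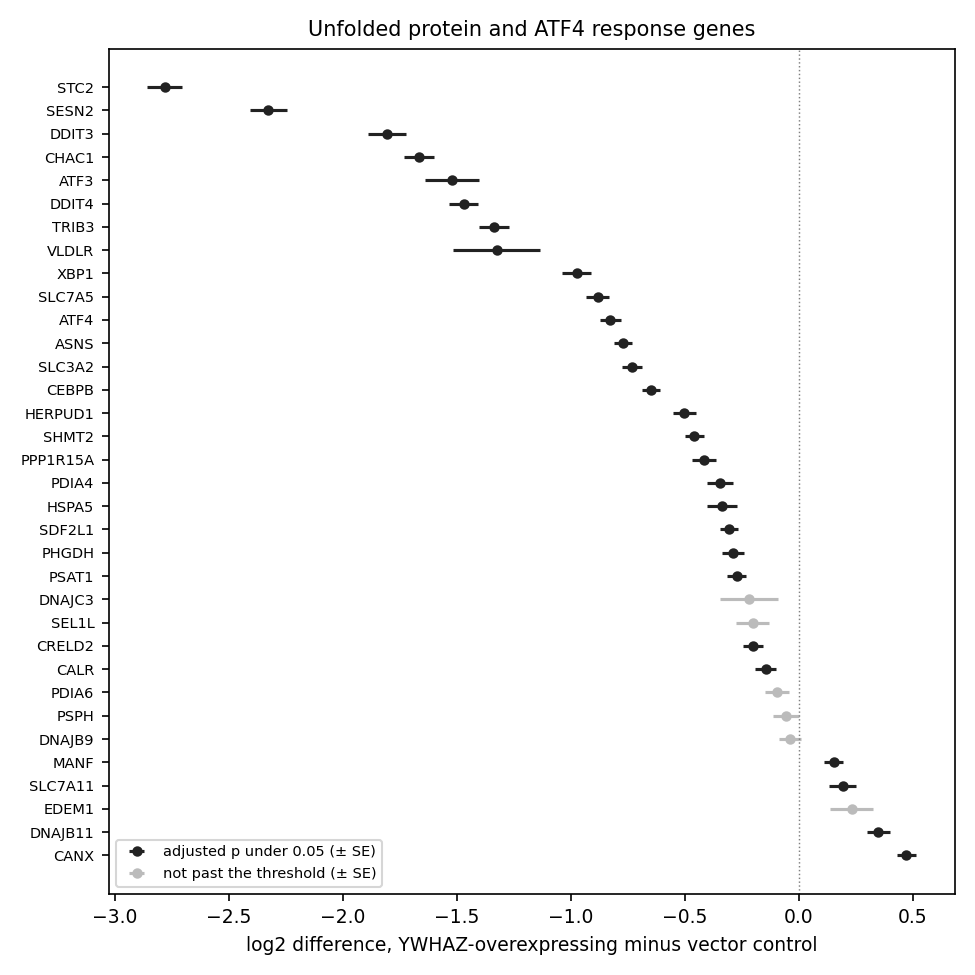
Log2 difference (YWHAZ-overexpressing minus vector control) of the 34 kept genes of the unfolded protein and ATF4 response list, with horizontal bars of ± SE from limma, n = 3 per group. Black marks genes with an adjusted p under 0.05 and grey those that did not pass; 24 black points lie below 0, led by STC2 at -2.78, and 4 lie above it.

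Genes of the oxidative stress response controlled by NRF2 fell as well. Of 18 kept, 13 fell, 3 rose and 2 did not pass, with the same counts adjusted over the list alone, and the median was -0.22. AKR1C1 fell by 2.09 on the log2 scale (4.26-fold, adjusted p = 4.23e-05) and AKR1C2 by 1.43 (2.69-fold, adjusted p = 0.00121, and 0.0567 with trended and robust variance). These aldo-keto reductase genes are near-identical and their probe sets are of the type that can bind several transcripts, so the pair is best read together. GCLC, the catalytic subunit of glutathione synthesis, fell 1.86-fold (-0.90 ± 0.044, adjusted p = 1.73e-05) through 202922_at and 202923_s_at, while 1555330_at stood at -0.078 (adjusted p = 0.364). OSGIN1 fell by 0.81 (adjusted p = 4.53e-05). Camera passed the list as lower (adjusted p = 0.00293). The call is lost with an estimated correlation (adjusted p = 0.357) and if the probe set with the highest mean ratio stands for each gene (adjusted p = 0.271), and the hybridisation controls differed by -0.84 between the same samples.

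Lung epithelial lineage genes passed as lower on the strength of a pair of members. Of 10 kept, FOXA1 and CAV1 fell, none rose and 8 did not pass, with the same counts adjusted over the list alone. CAV1 marks flat alveolar (type I) cells in lung and is also common in other cell types. The median was -0.10 and camera's adjusted p = 0.0261. The call is lost with an estimated correlation (adjusted p = 0.357), on ranks (adjusted p = 0.0788) and with the probe set of highest mean ratio (adjusted p = 0.167). The control differences of -0.84 and 0.49 apply here too.

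Several signalling programmes held large changes in single genes that ran both ways, and camera passed none of them. Among 19 ERK/MAPK response genes, 5 rose, 7 fell and 7 did not pass, the same adjusted over the list alone (camera adjusted p = 0.497). HBEGF, a ligand of the EGF receptor, rose 5.05-fold (2.34 ± 0.089, adjusted p = 6.07e-06), and the feedback inhibitor gene SPRY4 fell 2.37-fold (-1.24 ± 0.097, adjusted p = 0.000115). Of 20 YAP/TEAD target genes, 9 rose, 6 fell and 5 did not pass, also adjusted over the list alone (adjusted p = 0.912). AMOTL1 rose 2.86-fold (1.51 ± 0.23, adjusted p = 0.00184), MYOF 2.45-fold (1.29 ± 0.16, adjusted p = 0.000717), and DOCK5 fell 2.04-fold (-1.03 ± 0.048, adjusted p = 1.48e-05). In the TGF-beta list, 9 of 26 genes rose, 7 fell and 10 did not pass under either adjustment, over all genes or adjusted over the list alone. BAMBI, a decoy receptor of the pathway, rose 3.12-fold (1.64 ± 0.14, adjusted p = 0.000159), and THBS1, which encodes thrombospondin-1, fell by 0.89, with 201110_s_at at -2.47 and its other probe sets at -0.059 and -0.16. The TGF-beta list's median of 0.080 and mean of 0.057 were positive, while camera ranked it lower (adjusted p = 0.985) and fry higher (adjusted p = 0.0192). Camera's direction is relative to the other genes, and fry's is relative to no change.

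Growth control and death genes also changed both ways. Of 25 FOXO and PI3K-AKT genes, 4 rose, 7 fell and 14 did not pass, the same adjusted over the list alone (camera adjusted p = 0.350). BCL6 fell by 0.87 (adjusted p = 0.000644), and CDKN1B, the cell cycle inhibitor p27, rose by 0.66 ± 0.056 (adjusted p = 0.000162). Of 17 p53 target genes, 4 rose and 4 fell, and 9 did not pass, the same adjusted over the list alone (adjusted p = 0.350). ZMAT3, an RNA-binding p53 target, rose by 0.58 ± 0.096 (adjusted p = 0.00248), a call lost if its probe set with the highest mean ratio alone stands for it (0.13, adjusted p = 0.116). Besides SESN2, GADD45A fell by 0.56 (adjusted p = 0.000186) and CDKN1A, the inhibitor p21, by 0.47 (adjusted p = 0.00482). Among 25 BCL2 family and caspase genes, 7 rose, 4 fell and 14 did not pass under both adjustments, over all genes and adjusted over the list alone (adjusted p = 0.963). The pro-apoptotic PMAIP1 fell 2.11-fold (-1.08 ± 0.10, adjusted p = 0.000249) and BIK 1.68-fold (-0.75 ± 0.11, adjusted p = 0.00142), and CASP9 rose by 0.56 ± 0.063 (adjusted p = 0.000472). CASP8 rose by 0.73 ± 0.062 through 213373_s_at (1.53), whereas 1553306_at stood at -0.076 and reverses the gene's direction if used alone. That list's median and mean were just above 0 while camera, which compares it with the other genes, ranked it lower. The median of all genes tested was 0.038.

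Metabolic, housekeeping, interferon and cytokine lists held some changed genes and did not pass camera. Of 27 hypoxia and glycolysis genes, 9 rose, 6 fell and 12 did not pass, the same adjusted over the list alone (camera adjusted p = 0.497); the peptide hormone gene ADM rose 2.12-fold (1.08 ± 0.057, adjusted p = 2.46e-05) and P4HA2, a collagen prolyl hydroxylase, by 0.65 ± 0.064 (adjusted p = 0.000274). Among 24 genes of cholesterol and fatty acid synthesis, 9 rose, 1 fell and 14 did not pass, the same adjusted over the list alone (adjusted p = 0.350). STARD4, a sterol carrier, fell by 0.72 (adjusted p = 0.000278), and ACLY, which makes cytosolic acetyl-CoA, rose by 0.43 ± 0.048 (adjusted p = 0.000447). Without the range filter both lists passed as higher, at an adjusted p = 0.0417 and 0.00763; with the filter and an estimated correlation the adjusted p = 0.574 and 0.622. Of 16 ribosomal protein genes, 5 rose, 2 fell and 9 did not pass (6 and 3 adjusted over the list alone; camera adjusted p = 0.649), with RPL38 lower by 2.23-fold (-1.16 ± 0.059, adjusted p = 2.12e-05) on both probe sets. Interferon-stimulated genes had 5 of 19 higher, 1 lower and 13 not past the threshold, the same adjusted over the list alone (adjusted p = 0.963): the immunoproteasome gene PSMB9 rose by 0.85 ± 0.12 (adjusted p = 0.00146) and ISG15 by 0.64 ± 0.046 (adjusted p = 8.32e-05), while IFI35 fell by 0.47 (adjusted p = 0.00119). In the NF-kB and cytokine list, 1 of 11 genes rose, 2 fell and 8 did not pass (0 and 2 adjusted over the list alone; adjusted p = 0.350), NFKBIA falling by 0.44 (adjusted p = 0.000925), through 201502_s_at at -0.76 and not through 231699_at at -0.11.

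Markers of other cell types changed in a few genes, and no such list passed. Of 9 kept fibroblast and stromal genes, 2 rose (COL3A1 and POSTN), 7 did not pass and none fell, the same adjusted over the list alone (camera adjusted p = 0.845). Endothelial and leukocyte markers kept only 4 genes each, too few for a list test. ERG rose among the endothelial ones and CORO1A fell by 0.37 (adjusted p = 0.00331) among those of leukocytes, while 3 in each list did not pass; these counts are the same adjusted over the list alone. Of 6 neuroendocrine genes, 2 fell and 4 did not pass (3 fell adjusted over the list alone; camera adjusted p = 0.149), the secretory granule gene CHGA by 0.45 (adjusted p = 0.00104) and the vesicle gene SYP by 0.40 (adjusted p = 0.00645). Over all 26 lists tested, 4 passed camera, 1 higher and 3 lower, against 6 at an unadjusted p under 0.05. With an estimated correlation 0 passed, with 3 at an unadjusted p under 0.05, and fry passed 21.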

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

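In this part the test of the hybridisation controls and the counts of splits for probe sets and genes were chosen after the results were seen; the splits for 2-fold genes and lists and the test of 3′ bias were written down beforehand.

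A pair of control measures outside the gene comparison separated the groups. The 5′ minus 3′ log2 difference of the ACTB controls was higher in YWHAZ samples by 0.487, and that of the GAPDH controls by 0.251, both above the level in the vector controls and with no overlap between the 3 arrays of each group.

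As many as 5417 genes differed between the groups, and the bacterial hybridisation controls differed with them, by -0.844 on the log2 scale. A difference in labelling or hybridisation between the groups is a candidate explanation for part of the many small changes, and it cannot be told apart from the effect of YWHAZ, because each group lies entirely on one side. For a shift in 3′ bias, the prediction was that probe sets of one gene disagree. It was examined in 309 genes with a probe set called at least 2-fold and another kept. Of their 596 other probe sets, 86.4% went the same way (exact 95% binomial interval 83.4% to 89.1%, counting probe sets as independent). Probe positions were not used, and probe sets equally far from the 3′ end would agree under such a shift too. The agreement therefore cannot decide whether 3′ bias contributed. Of the 10 splits of the 6 samples into 3 and 3, 1 (the real one) gave 9983 probe sets, 5417 genes and 252 genes of at least 2-fold. The highest of the others gave 0. For lists 1 split gave 4 and the highest other 2, and most other splits gave 1. Every other split mixes the groups, so the group difference widens its spread and lowers its gene calls. The 0 there therefore does not show what chance gives, and 10 splits are too few for a share under 0.05. The effect of YWHAZ itself remains open as a biological account, as does a difference between the cell populations.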

How the results depend on the processing

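The range filter of 1.2-fold, the probe set with the largest range and camera on ranks were chosen after seeing the data; the other alternatives were planned. YWHAZ had 3 probe sets past the threshold in every setting that tests probe sets; the choice of probe set per gene and the set tests do not touch this count. The counts of probe sets and of genes past the threshold, in total and per direction, stayed within 1.5 times their main values in every setting that computes them, and the share of called genes that were higher ran from 60.7% to 65.6%. Leaving out each sample in turn gave 8157 to 8969 probe sets (4931 to 5375 higher, 3090 to 3630 lower), 4520 to 4896 genes (2870 to 3068 higher, 1558 to 1828 lower), 247 to 263 genes of at least 2-fold (118 to 129 higher, 126 to 135 lower), 3 to 4 lists (0 to 1 higher, 3 lower throughout) and 3 YWHAZ probe sets. Genes of at least 2-fold numbered 159 (69 higher) without a filter and with the planned filter as written. They numbered 66 (25 higher, 41 lower) on log2 of the ratio plus 1 and 0 (0 higher, 0 lower) on log2 of the ratio plus 16, where limma still called 5305 genes, since an added constant shrinks every ratio toward 1. With the probe set of largest range they numbered 458 (239 higher, 219 lower), which follows from choosing the widest. Lists past the threshold numbered 8 (5 higher) without a filter or with the planned one, 2 (0 higher) with the stricter planned filter, and 1 (0 higher, 1 lower) with the probe set of highest mean. No list, that is 0, was higher with the 1.2-fold range filter, quantile normalization or the probe set of largest range. With an estimated correlation camera passed 0 lists (0 higher, 0 lower; 3 at an unadjusted p under 0.05), and fry passed 21 (11 higher, 10 lower). Fry asks whether the genes of a list differ between the groups, and camera whether they differ more than the other genes do. With 46.0% of all genes tested past the threshold, their counts answer unlike questions. The cause was not tested for the other list counts. Across 123 named genes and YWHAZ probe sets, 2104 of 2193 comparisons with an alternative (95.9%) kept direction and side of the threshold, 84 lost the call, 4 gained one and 1 reversed. LSS and NFKB1 lost it in 11 settings each, YWHAQ in 10, RPS16 in 9, USP18 in 7, CCNE2 and PKM in 6 each. The reversed gene was CASP8, at -0.0758 with the probe set of highest mean, a setting under which 23 other genes lost the call; the TGF-beta list reversed under fry, with an adjusted p of 0.0192 (0.0192 to 1.00 over the alternatives). Same-numbered samples did not deviate together (correlations across probe sets of 0.000547, -0.00688 and 0.0109, and no YWHAZ sample correlated best with its own number). No pairing by number was detected, which does not exclude that same-numbered samples were handled together. The replicate block gave 4908 genes, 63.9% higher, and ended the calls of RPS16 and YWHAQ. Signal over background is unknown here, so its limit on weakly expressed genes could not be judged.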

Other observations

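In this part the tests of gene order, of whole chromosomes and the split of ATF4 targets from chaperones were chosen after the results were seen; the correction for gene density and the regional correction of the ATF4 list were written down beforehand.

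Some further genes outside the lists changed by over 3-fold; they were picked for their size after their values were seen, and stand for no group. Endothelin-1 (EDN1) fell 5.53-fold (-2.47 ± 0.095, adjusted p = 6.20e-06) and the endothelin receptor gene EDNRB 3.99-fold (-2.00 ± 0.043, adjusted p = 3.60e-07), each on 3 probe sets. PROCR, the endothelial protein C receptor, fell 6.64-fold (-2.73 ± 0.17), and AGR2, a secretory pathway protein of epithelia, 5.14-fold (-2.36 ± 0.20). NTS, which encodes the peptide neurotensin, rose 5.31-fold (2.41 ± 0.048, adjusted p = 3.22e-07), ERBB4, a receptor of the EGF receptor family, 3.75-fold (1.91 ± 0.11), and FRZB, a secreted Wnt antagonist, 3.65-fold (1.87 ± 0.059). The interferon-induced membrane protein genes IFITM3 and IFITM2 fell 7.29-fold and 3.98-fold, each on 1 probe set (IFITM3 -2.87 ± 0.12, IFITM2 -1.99 ± 0.068); these genes are near-identical, so their separate values are uncertain. MARCKS, an actin-binding substrate of protein kinase C, rose 3.89-fold (1.96 ± 0.062) on all 4 kept probe sets, and S100A10, the annexin A2 partner, fell 4.58-fold (-2.19 ± 0.052). In each of these genes the 3 arrays of one group lay beyond the 3 of the other.

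Genes near each other on a chromosome changed together. Across 11732 placed genes the log2 differences of genes 20 apart had a Spearman correlation of 0.0868, against at most 0.0274 in 1000 random gene orders, so neither chance order nor local pairs alone account for it; genes are not independent replicates. After the trend with local gene density was removed the correlation was 0.0803, against at most 0.0279, which argues against gene density as the whole cause. On 8 of 23 chromosomes under 40% or over 60% of the genes were higher, where random assignments reached 3. Chromosome 22 had 20.7% higher and chromosome 7 35.3%, chromosomes 5 and 6 71.0% and 69.4%, and all placed genes 54.6%. Chromosomes 11 (60.3%) and 20 (61.5%) passed the bound narrowly and fell to 59.2% and 59.7% at the lowest with a sample left out. The shifts were small, with median log2 differences from -0.14 (chromosome 22) to 0.15 (chromosome 5). A hypothesis is that the transfectant populations may differ by chromosome gains and losses, as cells grown out under selection can, but no DNA copy number was measured and the expression effect of YWHAZ is not excluded.

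The unfolded protein and ATF4 list passed camera as lower with the preset correlation (adjusted p = 1.93e-09). It did not pass camera with an estimated correlation (adjusted p = 0.0907). Camera on ranks also passed the list (adjusted p = 8.30e-07). So did fry, as lower (adjusted p = 2.32e-05), but fry passed 21 lists. After subtracting the median of each gene's 40 nearest genes, the list's median was -0.41 against -0.38 before. Broad shifts shared by most of the 40 nearest genes therefore do not account for that lower median. Short runs of genes would hardly move the median of 40, so this correction cannot exclude them. Among its members, the median of 18 ATF4 targets was -0.83 and that of 14 chaperones and other endoplasmic reticulum genes -0.17, a difference of -0.65. Of the targets 16 fell and 1 rose; of the chaperones 6 fell and 3 rose. This split was drawn after the members' values were seen, so it tests nothing: a fall of the ATF4 branch and a fall of the whole stress programme both stay open, as does a contribution from labelling (hybridisation controls -0.844).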
